A study of Homo sapiens with 3 samples.

How the data were processed

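DDX6 eCLIP was done in HCT116 cells crosslinked with ultraviolet light of 254 nm at 400 mJ/cm2, per the labels' protocols. Immunoprecipitation used 2 different anti-DDX6 antibodies, per the labels' protocols, without saying which library had which. RNA was recovered from the gel above 54 kDa, per the labels' protocols. The submitters' processing notes name cutadapt 1.18, Bowtie2, STAR 2.7.8a and the hg38 build (GRCh38), without their roles. The peak caller and its settings are not given in the sources used here. The libraries were 2 DDX6 eCLIP replicates and 1 size-matched input, and the labels do not say whether the replicates came from separate cultures. Each replicate has one deposited peak list without a header, so peaks were called per replicate, and the input library itself was not analysed here.

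The deposited lists give, for each peak, a −log10 p value and a log2 fold of eCLIP over input; both units were read from the values and from the usual column order of eCLIP peak files, since the lists have no header. The −log10 p deposited by the authors was 0 for 35.2% of peaks in replicate 1 and 34.9% in replicate 2, and its ceiling was 400. The deposited log2 fold ran from −7.13 to 6.75 in replicate 1 and from −6.89 to 6.61 in replicate 2. Almost all folds (over 99% of peaks) equalled a ratio of whole reads times one constant, within a relative tolerance of 1e-09. The constant gave the depth ratio of eCLIP to input, and the commonest fold corresponded to 3 eCLIP reads over 1 input read. Both read numbers were then recovered from the fold and the p, taken as that of a 2-sided binomial test at the depth ratio or a chi-square test. They had to give the −log10 p within 0.01, or within 0.01 times its value where it was above 1. The recovery worked for 99.8% of peaks with a p under 1 in either replicate. An input count of 1 may stand for 0 reads raised to 1. Where the p was at its numerical floor, the read numbers are the smallest that give the fold, and are called lower bounds. Enriched peaks had a median of 82 eCLIP reads in replicate 1 and 70 in replicate 2, and 69.4% and 71.2% had under 3 input reads. Intervals of single folds are exact for the ratio of the 2 read numbers at 95% and cover counting error only.

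Enriched peaks had a log2 fold of at least 3 and a −log10 p of at least 3. A reproducible region is the union of enriched peaks of both replicates that share at least 1 base on the same strand (bedtools 2.31.1), and its fold per replicate is the highest of its peaks. Control peaks are merged deposited peaks enriched in neither replicate that overlap no enriched peak. They can include peaks with a −log10 p of at least 3 and a log2 fold under 3. In replicate 1, 23698 peaks had that −log10 p and 8084 were enriched, and in replicate 2 19178 and 6635. The midpoint of each peak was assigned to GENCODE release 29 on GRCh38 on its strand, in the order coding sequence, 3′ UTR, 5′ UTR, non-coding exon, intron and intergenic, without read-through transcripts. Gene symbols came from the gene name table given with the reference. Peaks whose midpoint lay in the same region class of more than 1 gene were 1.19% in replicate 1 and 1.13% in replicate 2, and 5 reproducible regions were of this kind. No genome sequence was given, so GC content and motifs were taken from spliced GENCODE transcript sequences.

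Chance overlap was estimated from 100 shuffles within gene and region class. Region classes were compared with controls by 2-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 6 classes, and log2 odds ratios have 95% Woolf intervals after adding 0.5 to each cell. Gene lists, 17 in number and fixed before the data were examined, were tested the same way among genes with a deposited exonic peak in both replicates, with adjustment over lists. Each list was also set against 10000 random lists of the same size matched on deposited peaks per gene in 20 bins, a permutation of list membership, with its own adjustment over lists. Motifs, 7 in number, were sought within 50 bases of the midpoint of 3′ UTR regions and controls. Differences of medians have 95% intervals from 1000 bootstrap samples of genes, and gene properties were tested with 10000 permutations within 5 strata of deposited peaks. Peaks and genes are not independent replicates, so these tests describe these libraries. With 1 group of 2 replicates, no test between groups of samples was made. The shared input was examined with 20 simulations of libraries without enrichment. In these, both replicates shared an input redrawn from a rate pooled over the eCLIP and input reads of each pair. The recovered input reads were also split at random between the replicates.

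Named genes followed a rule fixed before the data were examined: DDX6 and HMGA2, the 10 genes of highest reproducible fold (the lower of the 2 replicates), the 5 genes with most regions, and up to 4 members per list by fold. Alternatives fixed beforehand were a log2 fold of at least 1, a −log10 p of at least 5, an overlap of 50% of both peaks, each replicate alone, 3′ UTR before coding sequence, a background of at least 5 peaks per gene, 3′ UTR peaks only, pairs enriched in at least 1 replicate, and motifs in the peak itself. Controls of at least 40 eCLIP reads, at least 3 input reads, matching on 3′ UTR length, and a comparison of coding and UTR classes alone were chosen after seeing the data. Words of 25 bases in the regions of the 10 strongest genes and of pseudogenes were sought in annotated transcripts of other genes, also chosen after seeing the data. The result of 1 of the 7 motifs is not reported here.

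The code was tested on simulated data. With 20000 simulated peaks, both read numbers were recovered for 100% of the 12138 peaks with a p under 1. The simulated p came from the same test that the recovery inverts, so this checks the code and not the source of the authors' p. Of 500 peaks planted in both replicates, 99.8% lay in recovered regions. Among random gene lists over the 14145 background genes, 4% had a matched p under 0.05, and 98% of lists with added calls did. The first codon read as ATG in 99.4% of 56679 coding transcripts. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.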

Results

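DDX6, an RNA helicase of processing bodies (P-bodies) that acts in translational repression and mRNA decapping, was profiled by eCLIP in HCT116, an established human colon cancer cell line. eCLIP crosslinks a protein to RNA with ultraviolet light and sequences the RNA fragments that copurify with it. The series held 2 DDX6 eCLIP replicates and 1 size-matched input library. The question was which transcripts DDX6 binds in these cells, in a study of P-bodies and the epithelial-mesenchymal transition (EMT). Each replicate had one list of peaks, with a log2 fold over the input and a −log10 p per peak. Replicate 1 had 172696 peaks with a median length of 53 bases, and replicate 2 had 157242 peaks with a median length of 52 bases. Total read numbers were not in the files, but the folds were ratios of whole reads. They gave an eCLIP to input depth ratio of 3.76 in replicate 1 and 3.34 in replicate 2. All coordinates are on hg38 (GRCh38).

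At a log2 fold and a −log10 p of at least 3, DDX6 bound exons of 1677 genes reproducibly. EIF1, KPNA2, PHLDA1 and DNAJB1 were among those of highest fold. The number of genes depends on the threshold and was 3065 at a log2 fold of at least 1. The highest reproducible enrichment lay in the coding sequence of EIF1, a translation initiation factor (chromosome 17, 41690784 to 41690845), with a log2 fold of 6.75 in replicate 1 and 6.61 in replicate 2. KPNA2, an importin of nuclear transport, reached 6.23 and 6.17 in its coding sequence. PHLDA1 reached 6.23 and 5.98 in its 3′ UTR, and the co-chaperone gene DNAJB1 reached 5.95 and 6.0 in its coding sequence. HMGA2, an architectural chromatin protein and EMT driver, also stood among the 10 genes of highest fold within one region, with 5.91 and 5.82. The others were DNMBP, the histone methyltransferase gene KMT2A, HEXIM1, FEM1C and BHLHE40, and their lowest log2 fold in either replicate was 5.73. Apart from DNMBP in replicate 2, the input count behind these 10 folds was 1, taken as a lower bound. With these bounds, the 95% counting interval in replicate 1 was 4.26 to 12.06 for EIF1 and 3.24 to 11.04 for BHLHE40. The order of the 10 genes is thus uncertain. Sequence copies limit some of these calls: of the 25-base words in the region, 43.6% for EIF1, 77.9% for KPNA2 and 44.3% for DNAJB1 also stood in annotated transcripts of other genes, and 0% for the other 7 genes.

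Peaks counted as enriched had a log2 fold of at least 3 and a −log10 p of at least 3. Replicate 1 had 8084 enriched peaks (4.68%) and replicate 2 had 6635 (4.22%). Of the enriched peaks of replicate 1, 5272 (65.2%) shared at least 1 base with an enriched peak of replicate 2. Shuffling the positions within the same gene and region class gave a mean of 1764 over 100 shuffles, with a maximum of 1850. Moving the enriched calls among the deposited peaks of the same gene and class gave a mean of 2709 and a maximum of 2773. Merging overlapping enriched peaks of both replicates gave 3976 reproducible regions with a median length of 106 bases. They lay in exons of 1677 genes, 11.9% of the 14145 genes with a deposited exonic peak in both replicates. Of these genes, 861 had 1 region and 207 had 5 or more. KMT2A had 30 regions, followed by the ankyrin repeat gene ANKRD17 with 19 and the zinc finger gene ZNF646 with 17. The corepressor gene SIN3A and the acetyltransferase gene CREBBP had 16 each. Regions that touch count separately, and joining them left 3797. The enriched peaks rested on few input reads: 42.0% in replicate 1 and 43.7% in replicate 2 had an input count of 1. In the EIF1 region at least 405 eCLIP reads stood over at least 1 input read in replicate 1, both lower bounds. With those numbers the 95% interval of its log2 fold ran from 4.26 to 12.06. Requiring at least 3 input reads in both replicates, with lower bounds taken as they stand, left 1143 regions in 548 genes.

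Log2 folds correlated between the replicates across peaks, and part of this correlation came with the shared input. Over 67703 pairs of overlapping peaks, Pearson's r was 0.90 and Spearman's rho was 0.89, and among the 3483 pairs enriched in at least 1 replicate they were 0.61 and 0.57. These are correlations across peaks, which are not independent replicates. Both replicates appear to have been set against one input, since 95% of 977 peaks with identical coordinates had the same input read number. Shared input reads raise the correlation. Among 41569 pairs with both read numbers, r was 0.87 and the covariance was 0.70. Libraries simulated without enrichment, with 1 redrawn input shared by both replicates, gave 0.79 and 0.37. The covariance exceeded the simulated one by 0.33, but the 2 sets are unlike. Observed pairs were kept only where the fold and p gave both read numbers, and the simulated pairs had no such filter. Over all 67703 pairs the observed covariance was 1.51. In 3403 pairs with at least 10 input reads, splitting those reads at random between the replicates lowered the covariance from 0.40 to 0.28 and r from 0.89 to 0.37. Splitting also leaves fewer input reads behind each fold, which lowers r by itself, so the fall in r does not measure the sharing. These pairs leave out the many enriched peaks with few input reads. Both replicates were enriched in 1743 of the 41569 pairs, against a mean of 0.25 and a maximum of 1 in 20 simulations. Calls had to pass a p under nearly the counting model that was simulated, so the low simulated number largely follows from the threshold. Enriched exonic peaks lay in 2518 genes in replicate 1 and 2068 in replicate 2, and 1784 genes were shared, against 368 for independent gene lists, a number that leaves out the shared input and the unequal number of peaks per gene.

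**Figure D1:**
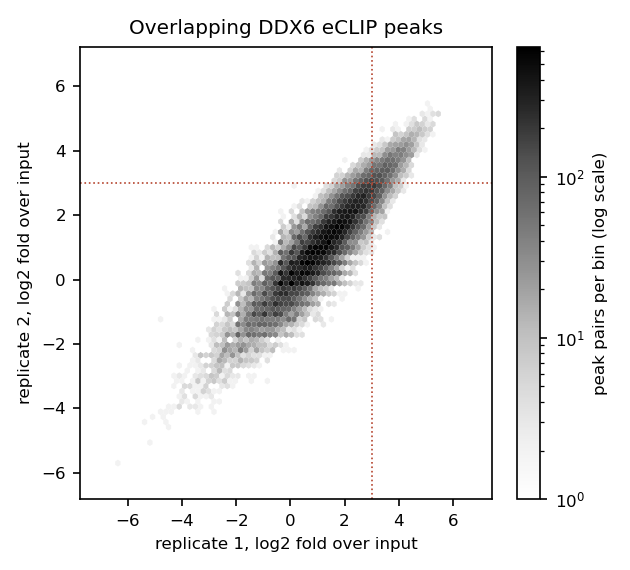
Log2 fold over input of 67703 overlapping peak pairs in replicate 1 (x axis) and replicate 2 (y axis), with the number of pairs per bin in grey on a log scale and dotted lines at the log2 fold threshold of 3. The pairs lie along the diagonal, with Pearson's r of 0.90.

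DDX6 regions lay in mature messenger RNA, mostly in coding sequence, and hardly in introns or non-coding exons. Coding sequence held 2916 of the 3976 reproducible regions (73.3%) and the 3′ UTR held 835 (21%). The 5′ UTR held 200 regions (5.03%), non-coding exons 18 (0.45%) and introns 7 (0.18%). Against deposited peaks enriched in neither replicate, the 3′ UTR was over-represented, with 21% against 14.2% (log2 odds ratio 0.68, 95% interval 0.57 to 0.80, adjusted p = 2.9e-30, 2-sided Fisher's exact test). Introns were under-represented, with 0.18% against 17.3% (log2 odds ratio −6.79, adjusted exact p = 1.2e-307). Non-coding exons were too, with 0.45% against 5.57% (log2 odds ratio −3.66, adjusted exact p = 3.3e-71). The 5′ UTR did not pass the test (log2 odds ratio −0.18, adjusted exact p = 0.11). Coding sequence stood at 73.3% against 57.2% (log2 odds ratio 1.04, adjusted exact p = 8.9e-97). Its log2 odds ratio was 0.53 in replicate 1 alone and 0.73 in replicate 2 alone, and the excess was not seen against deep controls. Against 38854 controls with at least 40 eCLIP reads, the log2 odds ratio of coding sequence was 0.023 (adjusted exact p = 0.82), that of introns −1.84 (adjusted exact p = 4.3e-05) and that of the 5′ UTR −0.62 (adjusted exact p = 2.3e-09). The 3′ UTR then stood at 0.39 (adjusted exact p = 5.6e-10) and non-coding exons at −2.00 (adjusted exact p = 9.2e-13). Deep controls can include peaks with a −log10 p of at least 3 and a log2 fold under 3. An equal share of coding sequence among them thus does not show that coding sequence lacks enrichment. With at least 3 input reads in regions and in these controls, the 5′ UTR deficit was not seen (0.027, 95% interval −0.29 to 0.35). The 3′ UTR stood at 0.42 and non-coding exons at −3.96 in that setting. These tests treat peaks as independent. The 3′ UTR share of enriched peaks was 22.9% in replicate 1 (exact 95% interval 22.0 to 23.9%) and 18.4% in replicate 2 (17.4 to 19.3%). The 2 antibodies are not assigned to libraries, so a difference between replicates cannot be separated from one between antibodies.

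**Figure D2:**
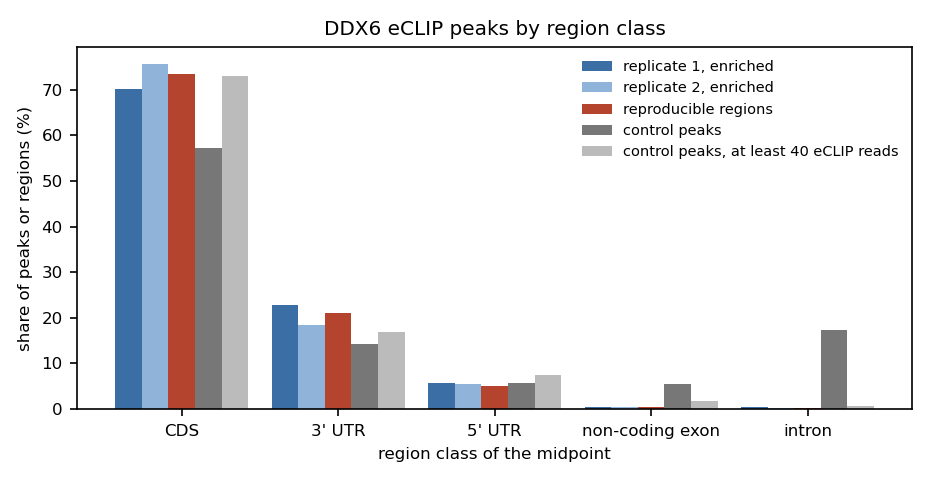
Share of peaks or regions (y axis, percent) by region class of the midpoint (x axis), for the enriched peaks of each replicate, the reproducible regions, all control peaks and control peaks with at least 40 eCLIP reads. The 3′ UTR holds 21% of reproducible regions and 14.2% of all controls, and introns hold 0.18% and 17.3%.

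Few non-coding RNAs carried reproducible regions. The snoRNA host transcript SNHG1 had 3 regions, with log2 folds up to 3.84 in replicate 1 and 3.88 in replicate 2. NORAD, a long non-coding RNA, had 1 region with 4.51 and 3.96. SNHG16 and LINC01234 also had regions. The pseudogenes EIF1P7, NPM1P32 and HSPA8P7 had regions too. Of the 25-base words in these regions, 73.7% stood in EIF1, 100% in NPM1 for the longer NPM1P32 region and 62.4% in HSPA8, so these calls and those of the parent genes are uncertain. Introns of 6 genes held the 7 intronic regions, and the strongest were a pair in RPRD2, with 4.76 in replicate 1 for both and 4.49 and 4.24 in replicate 2.

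HMGA2, which promotes EMT, had enriched peaks in its 5′ UTR, its coding sequence and part of its 3′ UTR. Of its 26 exonic peaks in replicate 1, 22 were enriched, and the median log2 fold was 3.90. In replicate 2, 20 of 27 were enriched, with a median of 3.72. Its lowest exonic log2 fold was 2.54 in replicate 1 and 1.97 in replicate 2. Its 11 reproducible regions fell in the 5′ UTR (3), the coding sequence (5) and the 3′ UTR (3), and joining those that touch left 9. Its peaks from transcript base 1064 to 1253, around the start codon, lay below the fold threshold. In the 3′ UTR, neither replicate had a peak between the one ending at base 1967 and those starting at base 3637, or after base 3742 of 4473. The strongest HMGA2 region spanned the stop codon, with its midpoint in the 3′ UTR (chromosome 12, 65963245 to 65963362; transcript bases 1423 to 1540, where the coding sequence ends at 1467). It had at least 227 eCLIP reads over at least 1 input read in replicate 1, and at least 188 over at least 1 in replicate 2. With these lower bounds, the counting interval of its log2 fold ran from 3.42 to 11.22 in replicate 1. DDX6 eCLIP also recovered the DDX6 message itself, with 4 regions in its 3′ UTR and 2 in its coding sequence. The strongest (chromosome 11, 118751747 to 118751895) lay in the 3′ UTR, with a log2 fold of 5.58 in replicate 1 and 5.43 in replicate 2. Of the 31 exonic DDX6 peaks of replicate 1, 11 were enriched, and of the 28 of replicate 2, 8 were. With at least 3 input reads in both replicates, 1 DDX6 region was left.

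**Figure D3:**
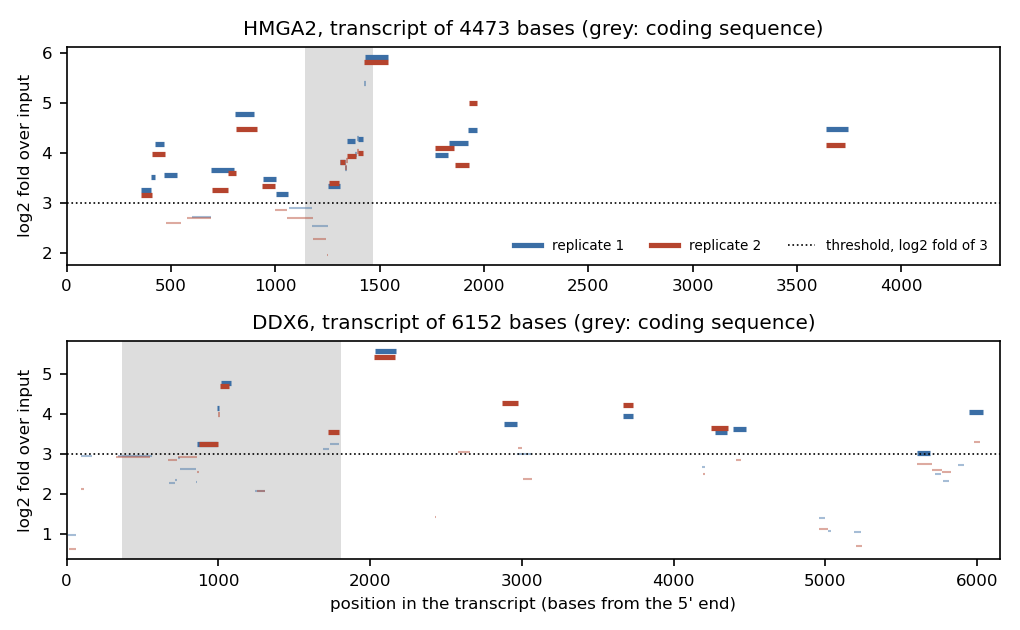
Peaks of each replicate on the HMGA2 transcript of 4473 bases and the DDX6 transcript of 6152 bases (x axis, bases from the 5′ end), drawn at their log2 fold over input (y axis), with thick lines for enriched peaks, grey for the coding sequence and a dotted line at the threshold of 3. The highest HMGA2 peaks, at 5.91 and 5.82, span the end of its coding sequence and the start of its 3′ UTR.

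Messages of the P-body and mRNA decay machinery were bound more often than other genes. Of the 60 background genes on this list, 26 had a reproducible region (43.3% against 11.9% of all background genes, log2 odds ratio 2.53, 95% interval 1.80 to 3.27, adjusted p = 7.3e-09, 2-sided Fisher's exact test). After DDX6, the strongest were TOB1, an adaptor that recruits the deadenylase (5.45 and 5.24), and ZFP36 and ZFP36L1, which bind AU-rich elements (5.44 and 5.22, 5.15 and 5.45). Others were the argonaute gene AGO2, and CNOT1, CNOT2, CNOT3, CNOT4 and CNOT8 of the deadenylase complex, named after their values were seen. AGO1, AGO3 and AGO4 had no reproducible region at the main threshold, nor did CNOT6, CNOT6L, CNOT7, CNOT9, CNOT10 and CNOT11. The decapping gene DCP2 and the exonuclease gene XRN1, also named afterwards, had no exonic peak with a −log10 p of 3. Random lists matched on deposited peaks per gene held a mean of 13.7 bound genes (adjusted permutation p = 0.0017). The call ended when only 3′ UTR peaks were used, with 8 of 45 genes (adjusted exact p = 0.24). With at least 3 input reads, 11 genes were bound (log2 odds ratio 2.55) and the matched test gave an adjusted permutation p of 0.10. At a log2 fold of at least 1, 35 of the 60 genes were bound (log2 odds ratio 2.34, adjusted exact p = 4.2e-09, matched adjusted permutation p = 0.0093). A gene without a region at the main threshold may thus still be enriched, and expression was not measured.

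EMT transcription factors and drivers were also bound more often. Reproducible regions lay in 14 of 31 (45.2%, log2 odds ratio 2.63, 95% interval 1.63 to 3.64, adjusted exact p = 1.6e-05), against a matched mean of 6.98 (adjusted permutation p = 0.016). After HMGA2, the strongest were the AP-1 gene FOSL1 (5.12 and 4.98 in one region), SOX9 (5.18 and 4.75) and FOSL2 (4.56 and 4.99). The highest enriched FOSL1 peaks, at 5.90 in replicate 1 and 6.23 in replicate 2, lay in no common region. With 3′ UTR peaks alone, 10 of 22 were bound (adjusted exact p = 1.1e-04). With at least 3 input reads, 7 were bound (log2 odds ratio 2.94, adjusted exact p = 6.3e-04) and the matched adjusted permutation p was 0.10. The repressors of E-cadherin SNAI1, ZEB1 and TWIST1, named after their values were seen, had no exonic peak with a −log10 p of 3 in either replicate. Of the TGF-β pathway, 6 of 29 genes were bound (adjusted exact p = 0.21), led by TGIF1 (4.53 and 4.69) and the inhibitory SMAD7 (4.48 and 4.19), with SMAD2 (4.0 and 4.12) and SMAD3 (3.95 and 3.69). SMAD2 and SMAD3 stood on both lists. Of the mesenchymal markers, 2 of 21 were bound, PLAUR (4.30 and 4.35) and CD44 (3.70 and 3.88). Of the epithelial junction and cytoskeleton genes, 9 of 53 were bound (adjusted exact p = 0.34), led by the catenin gene CTNND1 (4.93 and 4.47), ELF3 (4.50 and 4.47), the desmoplakin gene DSP (3.84 and 3.99) and KLF4 (3.72 and 3.85). The epithelial list passed without replicate 2 (adjusted exact p = 0.0082) and at a log2 fold of at least 1 (adjusted exact p = 0.0020), but not against matched lists (adjusted permutation p = 0.88 and 0.70).

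Cell cycle regulators were bound in 19 of 45 cases (log2 odds ratio 2.46, 95% interval 1.62 to 3.31, adjusted exact p = 1.5e-06), against a matched mean of 7.90 (adjusted permutation p = 0.0023). The replication licensing gene CDC6 reached 5.12 and 4.82 and the proliferation marker MKI67 reached 4.89 and 4.73. Cyclin B1 (CCNB1) reached 5.08 and 4.51, and the inhibitor CDKN1B reached 4.45 and 4.61. Zinc finger genes with ZNF symbols were bound in 73 of 365 cases (log2 odds ratio 0.93, adjusted exact p = 1.9e-05, matched mean 37.1, matched adjusted permutation p = 0.0017), led by ZNF574, ZNF24, ZNF142 and ZNF296. The zinc finger call ended with 3′ UTR peaks only (17 of 169, adjusted exact p = 1.00), with at least 3 input reads (adjusted exact p = 0.82) and at a log2 fold of at least 1 (adjusted exact p = 0.14). At that fold the matched test still passed, with 92 bound and an adjusted permutation p of 0.010.

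Chromatin regulators had the largest log2 odds ratio of the 17 lists, but they also had many deposited peaks. Of 67, 31 were bound (log2 odds ratio 2.7, adjusted exact p = 4.2e-11), led by KMT2A, ASXL2 (5.23 and 5.14), CHD7 (5.47 and 5.04) and TET3 (4.93 and 5.28). Matched random lists held a mean of 24.1, which left an adjusted permutation p of 0.26. Wnt and intestinal stem cell genes were bound in 11 of 37 cases (log2 odds ratio 1.70, adjusted exact p = 0.0061), with TCF7L2 at 5.40 and 5.07, BCL9L at 5.29 and 4.86, AXIN2 at 4.37 and 4.96 and BCL9 at 4.22 and 4.12. Their matched mean was 8.58 (adjusted permutation p = 0.78). Ubiquitin ligases were bound in 10 of 40 cases (log2 odds ratio 1.36, adjusted exact p = 0.038), led by RNF111, SIAH1, RNF4 and TRIP12, with a matched mean of 9.72 (adjusted permutation p = 1.00). With a background of at least 5 peaks per gene, the Wnt and ubiquitin ligase calls ended (adjusted exact p = 0.099 and 0.38).

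Cytosolic ribosomal protein genes did not stand apart from other genes at the main threshold. Of 82, 9 were bound (log2 odds ratio −0.059, adjusted exact p = 1.00), led by RPL7L1, RPL7, RPL34 and RPL30. At a log2 fold of at least 1, 62 of the 82 were bound (log2 odds ratio 3.49, adjusted exact p = 3.9e-24, matched adjusted permutation p = 0.0017). Their exonic peaks had median log2 folds of 0.45 in replicate 1 and 0.19 in replicate 2, below the 0.96 and 0.92 of all deposited peaks. Calls at the lower fold thus rest on some of their peaks, and the matching covered the number of peaks but not their read depth. Nuclear-encoded oxidative phosphorylation genes were under-represented, with 3 of 86 (ATP5PD, UQCRFS1 and NDUFV3, log2 odds ratio −1.69, adjusted exact p = 0.021), but against matched lists the adjusted permutation p was 0.26. That call ended without replicate 1 (adjusted exact p = 0.37) and turned at a log2 fold of at least 1 (log2 odds ratio 0.34, adjusted exact p = 0.43). Of 25 housekeeping messages 5 were bound (adjusted exact p = 0.27), led by NPM1 (5.55 and 5.63), HSPA8 (5.53 and 5.39), YWHAZ (4.81 and 4.68) and LDHA (4.07 and 3.88). Housekeeping messages passed at a log2 fold of at least 1 (log2 odds ratio 3.45, adjusted exact p = 3.5e-08, matched adjusted permutation p = 0.0095) and with at least 3 input reads (log2 odds ratio 2.74, adjusted exact p = 0.0081), where the matched adjusted permutation p was 0.74.

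Histone messages, mitochondrial transcripts and small nuclear RNAs gave no regions. None of the 54 replication-dependent histone genes (adjusted exact p = 0.0054), 24 mitochondrially encoded genes (adjusted exact p = 0.16) or 81 small nuclear, nucleolar and 7SL RNAs (adjusted exact p = 2.2e-04) was bound. The last list was fixed with 7SK, but no 7SK gene was among the 81. Without replicate 2, the mitochondrially encoded genes passed as under-represented (adjusted exact p = 0.036). Without replicate 1, 3 of 25 mitochondrially encoded genes (log2 odds ratio −0.046, adjusted exact p = 1.00) and 1 of 146 small nuclear, nucleolar and 7SL RNAs were bound. A count of 0 allows shares of up to 5.56%, 12.5% and 3.70%. Matched random lists held means of 0.71, 0.41 and 0.33, so the number of deposited peaks alone leaves almost no calls to lose. Of 8 background genes on the list named nuclear long non-coding RNAs, only the snoRNA host transcript SNHG1 was bound. MALAT1, NEAT1, KCNQ1OT1, FTX, GAS5, PVT1 and TUG1 were not. Where the bound RNA lay in the cell was not measured.

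**Figure D4:**
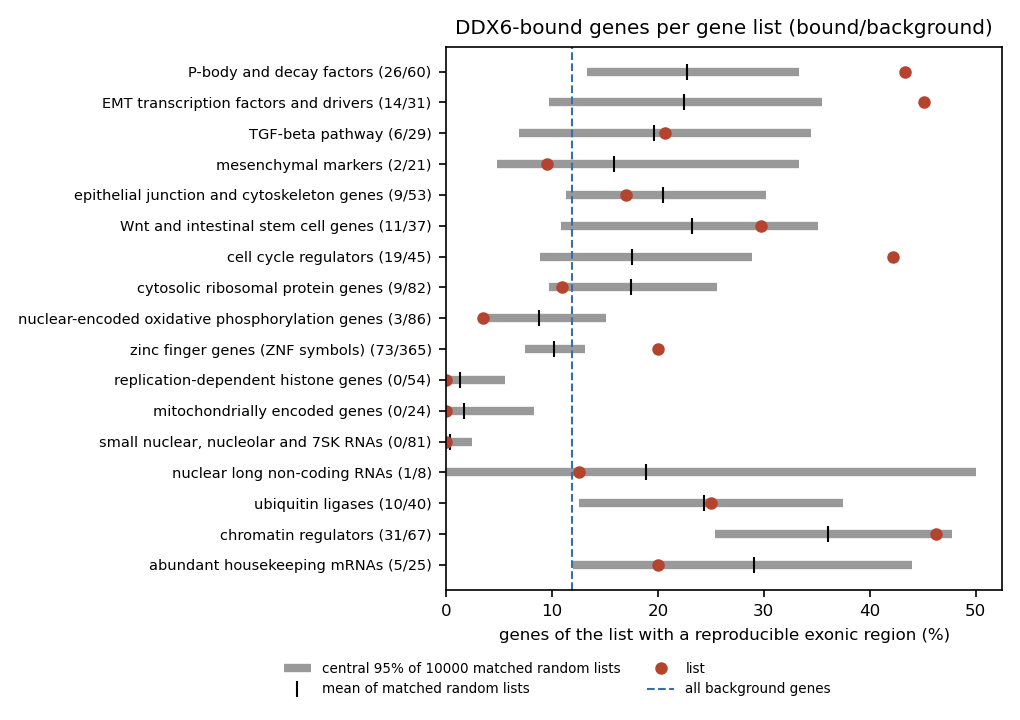
Share of the background genes of each list with a reproducible exonic region (x axis, percent; red points), beside the mean and central 95% of 10000 random lists matched on deposited peaks per gene (black ticks and grey bars) and the share over all background genes (dashed line, 11.9%). P-body, EMT, cell cycle and zinc finger genes lie above their matched ranges.

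Bound coding regions were slightly poorer in GC than controls, and 1 of the 7 motifs passed in the 3′ UTR. In coding sequence, 101-base windows around reproducible regions had a median GC content of 53.5% against 55.4% (difference −1.98 percentage points, bootstrap 95% interval −1.98 to −0.99). That difference was 0.00 at a log2 fold of at least 1 and −3.96 (−4.95 to −2.97) against deep controls. In the 3′ UTR the medians were both 56.4%, but the difference was −2.97 (−3.96 to −1.98) against deep controls and 3.96 (2.97 to 3.96) at a log2 fold of at least 1. Among the motifs, tested in 835 bound and 25682 control 3′ UTR windows, GCACUUU, the site of the miR-17 seed family, passed the threshold. It was in 0.84% of bound and 2.27% of control windows (log2 odds ratio −1.36, adjusted exact p = 0.027), and the call ended against deep controls (adjusted exact p = 0.92) and without replicate 1 (adjusted exact p = 0.070). The AU-rich pentamer AUUUA was in 3.71% against 4.73% (adjusted exact p = 0.64) and the let-7 site CUACCUC in 0.84% against 0.62% (adjusted exact p = 0.66). UAUUUAU, CAGUAUU and the polyadenylation signal AAUAAA did not pass either, with adjusted exact p of 0.97, 1.00 and 1.00. At a log2 fold of at least 1, AUUUA (log2 odds ratio −0.44, adjusted exact p = 0.013) and AAUAAA (−0.72, adjusted exact p = 0.0068) passed as depleted. Bound regions lay at a median relative position of 0.34 in the 3′ UTR against 0.38 for controls, and the interval of the difference, −0.08 to 0.00038, reached 0. It excluded 0 without replicate 1, where the difference was −0.044.

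Bound protein-coding genes had lower GC content and shorter coding sequences than their number of peaks predicts. The median transcript GC content was 50.1% in 1667 bound and 49.3% in 10023 other genes. Permuting the bound label within 5 strata of deposited peaks gave an expected difference of 2.24 percentage points, so the bound genes lay 1.47 points below it (excess −1.47, permutation p = 1.0e-04, the smallest that 10000 permutations can give). The direction turned at a log2 fold of at least 1, with an excess of 0.59 (permutation p = 0.024). Median coding length was 1629 bases in bound and 1326 bases in other genes, −144 bases relative to the strata (permutation p = 2.0e-04). The 3′ UTR length did not pass the test (excess −13.7 bases, permutation p = 0.71).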

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

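Controls of at least 40 eCLIP reads, at least 3 input reads (alone or with those controls), matching on 3′ UTR length and coding and UTR classes alone were chosen after seeing the data. No paired analysis was possible because the only group had 2 replicates and the single input had no file of its own. Under the alternatives, 52 of the 84 values of main results stayed on their side of the threshold or within 1.5 times, among them the 3′ UTR excess (log2 odds ratios 0.25 to 0.81) and the intron deficit. A log2 fold of at least 1 gave 23212 and 18732 enriched peaks, 11246 regions, 3065 genes and 3 motifs, all depleted (GCACUUU −1.24, AUUUA −0.44 and AAUAAA −0.72). The coding GC difference was then 0.00 (−3.96 against deep controls), that in the 3′ UTR 3.96 (−2.97 against deep controls), the excess at the last codon position 0.25, the 3′ UTR position passed (−0.045) and the excess in gene GC turned to 0.59. At that fold, ribosomal protein genes had a log2 odds ratio of 3.49 and 35.9 bound genes above their matched mean, oxidative phosphorylation genes 0.34, and housekeeping messages 7.02 genes above theirs. A −log10 p of at least 5 left 5174 and 4002 enriched peaks and 2407 regions. With at least 3 input reads, 2471 and 1911 enriched peaks, 1143 regions and 548 genes were left, no list was under-represented (0) and 1 list lay above its matched lists. With 3′ UTR peaks only, 3 lists passed, 0 were under-represented and 2 lay above matched lists; a background of at least 5 peaks left 1 under-represented. Correlations were 0.61 for pairs enriched in at least 1 replicate and 0.93 for 50% overlap. Motifs in the peak itself gave 5 passes, with AUUUA (log2 odds ratio 1.04), UAUUUAU (1.85) and AAUAAA (1.40) turning positive and CUACCUC (1.48) also passing, where regions were longer (median 106 bases) than controls (57). Against deep controls 0 motifs passed and coding sequence was at 0.023, and among coding and UTR classes alone coding sequence was at −0.031. With 1 replicate left out, regions ranged from 6635 to 8084, genes from 2068 to 2518, motifs from 0 to 1 and the 3′ UTR position from −0.044 to −0.016. Requiring fewer replicates or more reads changes how many peaks can pass, and the cause of the other changes was not tested. Few input reads limit the precision of single folds.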

Other observations

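The tests on further gene groups, with deep controls, with at least 3 input reads (alone or with deep controls), with matching on 3′ UTR length, without immediate-early genes and on the last codon position were chosen after results were seen. The 10 genes of highest fold and the 5 with most regions were left out of the further groups. Some other members, among them SPRY4, MED13L and genes of the lists fixed beforehand, belonged to results already seen, so the groups were also tested without the 15 genes of highest fold, the 15 with most regions and all genes of those lists (the narrower test). Immediate-early and signalling feedback genes were bound in 36 of 57 cases. Many immediate-early genes are switched on quickly by growth factors and encode short-lived messages. Lists matched on deposited peaks held a mean of 9.40 (percentile 100, adjusted permutation p = 0.0012). In the narrower test, 28 of 49 were bound against 7.17 (adjusted permutation p = 0.0012). This group was listed gene by gene after results were seen, so bound genes that were not left out could have shaped its membership. Its permutation p values are therefore descriptive. The feedback inhibitor ERRFI1 reached log2 folds of 5.47 and 5.31, the Sprouty gene SPRY4 5.31 and 5.21 with 10 of its 15 regions in the 3′ UTR, IER3 5.26 and 5.19, and the transcription factor EGR1 5.13 and 5.18. The phosphatase gene DUSP6 reached 4.75 and 4.28. Chaperones and co-chaperones were bound in 19 of 63 cases against a matched mean of 8.83 (percentile 99.985, adjusted permutation p = 0.0018) and in 17 of 60 against 7.65 in the narrower test (adjusted permutation p = 0.0042), led by HSPA8 and the endoplasmic reticulum chaperone HSPA5 (5.22 and 4.77). Splicing factors of the SR and hnRNP families were bound in 14 of 35 cases against 7.72 (percentile 99.45, adjusted permutation p = 0.034), led by HNRNPU (4.90 and 5.03). The narrower test left out none of these genes, so it is no further check. All bound members except SRSF4 and SRSF7 were hnRNP genes, and the families were not tested apart. Chaperone and hnRNP genes have pseudogene copies, which leaves some of their calls uncertain.

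Other groups prompted by single strong targets did not stand above matched lists. The Mediator complex had 7 of 30 genes bound (percentile 91.9), translation initiation factors 14 of 53 (percentile 91.4) and importins and exportins 5 of 21 (percentile 50.7). In the narrower test their percentiles were 90.2, 85.2 and 55.5.

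The number of deposited peaks does not alone account for the P-body (percentile among matched lists 100), EMT (99.885), cell cycle (99.995) and zinc finger (100) lists. It could account for the chromatin regulator (96.4), Wnt (84.0) and ubiquitin ligase (55.0) lists, which were also bound more often by the exact test. The matched test was fixed beforehand, and this reading of its percentiles was set after the result was seen. With at least 3 input reads the log2 odds ratio was 2.55 for P-body (95% interval 1.62 to 3.48), 2.94 for EMT and 2.90 for cell cycle genes, so few input reads do not account for these alone, although the matched test then gave an adjusted permutation p of 0.10 for P-body and EMT genes; for zinc finger genes it was 0.23 (matched adjusted permutation p = 0.52), so few input reads could account for that call. Long 3′ UTRs do not account for the P-body list alone, with a percentile of 99.995 after matching on their length. Members of the immediate-early list used here, 4 on the P-body list and 2 on the EMT list, were not the whole cause. Without them the percentiles were 99.845 for P-body genes and 99.42 for EMT genes. Early genes that this list lacks would have stayed in, so the class as a whole was not tested. A candidate explanation is that DDX6 binds the messages of its own decay machinery and of EMT regulators, but expression was not measured here and no other condition was compared, so this stays open.

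Bound regions were nearly absent from introns. Shallow control peaks could inflate this, but against controls of at least 40 eCLIP reads the log2 odds ratio for introns was −1.84 (95% interval −2.89 to −0.79). Libraries simulated without enrichment gave a mean of 0.25 pairs enriched in both replicates, against 1743 observed. Each call had to pass a p under nearly the same counting model, and the simulated input came from a rate pooled with the eCLIP reads. The low number thus largely follows from the threshold. It cannot decide whether counting noise of the shared input gave shared calls. The eCLIP reads of the replicates also scattered beyond counting noise (chi-square of 1.86 per peak over 928 peaks), and such noise was not simulated. With at least 3 input reads in regions and in controls of at least 40 eCLIP reads, 0 of 1143 regions lay in introns. From the controls 8.17 were expected (log2 odds ratio −4.04, 95% interval −8.05 to −0.040, adjusted exact p = 0.0014). The fold threshold takes at least 30.1 eCLIP reads per input read in replicate 1 and 26.7 in replicate 2. Controls could thus be shallower than any such region. The test therefore cannot say whether chance low input counts account for the deficit. The depth of the control peaks may account for part of the difference, since the log2 odds ratio was −6.79 with all controls. No biological explanation was tested.

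Bound genes had fewer G or C at the last codon position than their number of deposited peaks predicts. The median was 59.5% in 1650 bound and 60.3% in 9904 other genes, and the difference lay at −3.66 percentage points relative to the strata (permutation p = 1.0e-04, the smallest that 10000 permutations can give). It was lower in 5 of 5 strata, by −8.88 to −2.53 points. The number of peaks does not account for this alone. At a log2 fold of at least 1 the pattern was not seen, with medians of 62.4% in 3006 bound and 59.1% in 8548 other genes and an excess of 0.25 points (permutation p = 0.65). The cause of this dependence on the threshold was not tested.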
